A study of Homo sapiens with 16 samples.

How the data were processed

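Expression was measured on 16 Illumina bead arrays, each hybridised with biotin-labelled cRNA made from total RNA of a human lymphoma cell line treated for 8 h. The arrays fell into 6 groups by the labels: HBL-1 with vehicle (4 arrays), MI-2 (3) or z-VRPR-fmk (1), and TMD8 with the same numbers. Doses and the vehicle's composition are not given in the sources used here. Nothing in the labels says that arrays of a group came from separate cultures, so p-values here measure only the spread between these arrays, which may be technical.

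Per the file headers, the authors deposited for each array and probe a signal intensity and a detection p-value. The intensities were linear and not normalized, with medians of 82.5 to 103 per array and no values at or below 0. The deposited detection p-values moved in steps of 1/770, and 34.1% to 40.8% of the 47323 probes per array had a detection p under 0.05. The authors also deposited a table of log2 values with 34687 named genes, of unstated processing, in which each array had a median of 6.50. Partek is named in the submitters' processing notes, without a version or a role. Probe annotation, slide and genome build are not given in the sources used here, so no coordinates are printed.

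The deposited intensities carry probe identifiers and the deposited log2 values carry gene names, so the 2 were joined by value. The log2 values followed the mean linear intensity of a gene's probes through a monotone curve fitted per array. Such a match does not show which background correction or normalization the authors used. Of the named genes, 34651 matched a probe or a set of probes within 0.02 log2 over all 16 arrays, 26193 of them a single probe and 8458 at least 2. After shuffling the arrays 0 matched. The 36 unmatched genes and the 56 probes without a gene name were left out, as were 92 spike-in controls. Of the matched names, 17563 are current RefSeq symbols, 2195 are a synonym of a current symbol and 14893 are in neither set. Names are printed as the files give them (ARMET is now called MANF).

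Intensities were corrected for background with limma's neqc (version 3.58.1, in R 4.3.3), which infers the background level from the detection p-values, with an offset of 16, and then quantile normalized and put on the log2 scale. Probes with a detection p under 0.05 on at least 3 of the 16 arrays were kept (22426), and a gene was represented by its probe with the highest mean level, which left 17570 genes. Of these, 3716 had more than 1 probe passing, and disagreement between probes is stated beside the gene. Changes were tested with limma (lmFit and eBayes) in a model of the 6 group means over all 16 arrays. For z-VRPR-fmk, with 1 array per line, the model held terms for line, MI-2, MI-2 by line and a z-VRPR-fmk effect taken as equal in the lines. Significance was a Benjamini-Hochberg adjusted p under 0.05 over all genes. Tests were two-sided, and adjusted p-values below are from limma. The number of arrays limits the precision: the median standard error of a log2 change was 0.157 for MI-2 in either line.

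Shifts of 24 gene lists were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. List means are means of the members' log2 changes. The lists were NF-kB targets, CBM complex and IKK activation, MALT1 substrates, Regnase-1 and Roquin mRNA targets, JAK-STAT3 targets, MAPK and AP-1 immediate early genes, NRF2 antioxidant response, heat shock response, metallothioneins and zinc export, amino acid and integrated stress response, endoplasmic reticulum unfolded protein response, p53 targets, S phase, mitosis, type I interferon response, ABC-type DLBCL genes, germinal centre B cell-type DLBCL genes, B cell receptor signalling and B cell identity, MYC targets and ribosome biogenesis, cholesterol synthesis, apoptosis regulators, glycolysis and hypoxia response, chemokines and cytokines with their receptors, and histone genes. The list called histone genes also held the histone deacetylase genes HDAC1, HDAC5 and HDAC9. Markers of T cells, NK cells, myeloid cells, erythroid cells, epithelial cells, fibroblasts and plasma cells were also listed. The comparisons, tests, lists, rule for named genes and most processing alternatives were fixed before the data were examined. Those added later are named as such in the closing section.

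The rule for named genes took, for MI-2 in either line, up to 10 rises and 10 falls past the threshold whose MI-2 arrays all lay beyond all vehicle arrays. For z-VRPR-fmk it took up to 10 per direction past the threshold and beyond all vehicle arrays in both lines, filled up to 5 per direction by size alone with genes said not to have passed. For the remaining comparisons it took the 5 largest per direction past the threshold. It always took 19 genes of this pathway and its targets where measured (MALT1, BCL10, NFKBIA, TNFAIP3, CYLD, RELB, ZC3H12A, IRF4, BCL2A1, CCL3, CCL4, IL6, IL10, CCND2, CD44, BCL2L1, MYC and HMOX1; CCL4 was not measured, and 1 further gene is not reported here), and per list the 4 members with the smallest p.

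A gene whose probe was not detected on any array of a group has only a bound there. Its fold is written as at least N-fold, the brighter group's mean over all arrays against the mean, over the dimmer group's arrays, of the higher of the lowest detected level of the array and the probe's own level. These lowest detected levels ran from 4.57 to 4.78 log2. Where only some arrays of a group detected a gene, their number is given and the fitted change includes levels near background.

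Arrays within a group correlated at 0.982 to 0.994 and no pair was identical. The labels number the arrays 1 to 4, and whether equal numbers mark paired arrays was checked on deviations from group means. The 6 same-numbered vehicle and MI-2 pairs correlated at 0.16 to 0.31, against -0.23 to 0.17 for the 18 pairs of different numbers, so the numbers were taken to pair the arrays. A fit with line and number as a block was run as an alternative. In it vehicle 1 to 3 pair with MI-2 and vehicle 4 pairs with z-VRPR-fmk. The pairing of the arrays numbered 4 could not be checked, since z-VRPR-fmk has 1 array per line. Unless the block is named, calls and p-values below are from the fit without it, which ignores the pairs. With the block limma called 0 genes in each treatment comparison, and 9 list results turned sign. The block leaves fewer residual degrees of freedom than the 10 of the model of 6 group means. A call lost with it may thus reflect lower power or a smaller effect, and the calls alone cannot tell these apart.

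The testing steps were tested on simulated data with 200 changed genes among the 17570. For MI-2 in HBL-1 29% of 1.5-fold and 84% of 2-fold changes were recovered with 5.04% false calls, in TMD8 29% and 80% with 1.80%, and for z-VRPR-fmk 30% and 86% with 4.92%. A shifted list was recovered in each of these comparisons and 0 unchanged lists were called. The simulated genes varied independently of each other and without pairing by number. The simulation therefore does not show how the list test behaves with correlated genes or paired arrays.

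Alternatives covered background correction, normalization, the authors' processed values, the detection filter, the choice of probe, the variance model, array weights, the arrays entering the fit, the replicate block, the correlation in the list test and leaving out each array in turn. Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1 joined the tables, and matplotlib 3.10.9 drew the figures.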

Results

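RNA levels were measured in HBL-1 and TMD8, established cell lines of activated B cell-like (ABC-type) diffuse large B cell lymphoma, after 8 h with a MALT1 inhibitor or vehicle. MALT1 is a protease and scaffold that, with BCL10, carries B cell receptor signals to NF-kB. MI-2 is a small-molecule MALT1 inhibitor, and z-VRPR-fmk is a peptide that blocks the MALT1 protease. Each line had 4 vehicle arrays, 3 MI-2 arrays and 1 z-VRPR-fmk array. Median signals were 82.5 to 103 per array and 34.1% to 40.8% of probes were detected, the lowest shares being on the HBL-1 arrays numbered 2 (vehicle 34.6%, MI-2 34.1%). Changes are log2 differences of normalized levels with their standard error (SE) from limma, and levels are given as mean ± SD. Markers of other cell types that were measured numbered 2 of 11 for T cells (CD2, CD8A), 3 of 7 for NK cells, 3 of 12 for myeloid cells, 4 of 7 for erythroid cells, 5 of 8 for epithelial cells, 2 of 7 for fibroblasts and 7 of 7 for plasma cells, and none was among the genes called in a treatment comparison.

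The first question was which transcripts differed between MI-2 and vehicle in HBL-1 cells. VPREB3, a partner protein of the pre-B cell receptor light chain, fell by 1.41 (SE 0.17, adjusted p = 0.00766), from 7.63 ± 0.17 in 4 vehicle arrays to 6.21 ± 0.43 in 3 MI-2 arrays. SLC5A5, the sodium-iodide symporter, fell by 0.86 (SE 0.12, adjusted p = 0.0271), from 5.50 ± 0.19 to 4.64 ± 0.17, and was detected on 4 vehicle arrays and 1 MI-2 array. Genes of the unfolded protein response and of the integrated stress response were higher as groups, each by 0.40 on average or 1.32-fold (adjusted p = 0.107 with an estimated correlation for each). ARMET, an endoplasmic reticulum stress protein now called MANF, was at 10.25 ± 0.14 with vehicle and 10.94 ± 0.11 with MI-2.

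VPREB3 and SLC5A5 were the genes past the adjusted threshold, both lower, among 17570 tested. At an unadjusted p under 0.05 there were 938 genes, against 878.5 expected by chance. The MI-2 and vehicle arrays did not overlap for 6.09% of genes, against 5.71% by chance. With the replicate number as a block limma called 0 genes, with 1259 at an unadjusted p under 0.05. VPREB3 then had an adjusted p of 0.41 (0.00043 to 0.41 over 31 alternatives, 27 of them past). SLC5A5 kept its call in 9 of 31 alternatives (adjusted p 0.0121 to 0.783) and lost it without any of 12 arrays, which left VPREB3 as the only call, except that GAS2L2 and ULBP1, named after their values were seen, were called beside it without MI-2 3. GAS2L2 was detected on 0 of 4 vehicle arrays and 2 of 3 MI-2 arrays. Leaving out HBL-1 vehicle 2, 3 or 4 gave adjusted p-values of 0.135, 0.169 and 0.0992 for SLC5A5, and leaving out MI-2 2 or 3 gave 0.179 and 0.171. Leaving out single TMD8 vehicle or MI-2 arrays gave 0.052 to 0.0586.

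All 21 measured members of the unfolded protein response list lay higher with MI-2 in HBL-1 (camera adjusted p = 1.15e-16; adjusted p = 0.107 with an estimated correlation). When adjusted over the list alone 8 rose: ARMET, the chaperones HSPA5, HYOU1, CALR and SDF2L1, the disulfide isomerase PDIA4, the co-chaperone DNAJC3 and the ubiquitin ligase SYVN1. None of them passed over all genes, except that ARMET did with trended and robust eBayes (adjusted p = 0.0356; 0.0356 to 1 over 31 alternatives, 1 of them past). ARMET was 0.69 higher (SE 0.13, adjusted p = 0.372), HYOU1 0.64 (SE 0.15, 0.596) and SDF2L1 0.60 (SE 0.15, 0.683). In the amino acid and integrated stress response list 29 of 30 members lay higher (camera adjusted p = 3.29e-18; adjusted p = 0.107 with an estimated correlation). When adjusted over the list alone 7 rose, namely AARS, CEBPB, DDIT3, PSAT1, PSPH, TRIB3 and VLDLR (detected on 1 of 4 vehicle arrays and 3 of 3 MI-2 arrays), and 0 passed over all genes. CEBPB, a transcription factor of stress and inflammation, was 0.64 higher (SE 0.15, adjusted p = 0.596). PSPH, the last enzyme of serine synthesis, was 0.89 higher (SE 0.20, adjusted p = 0.539), and its other probe 0.18. The mean of this list was 0.25 without MI-2 2 (adjusted p = 1.69e-08). With the replicate block both lists held their calls also with an estimated correlation (adjusted p = 0.0395 for each).

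**Figure D1:**
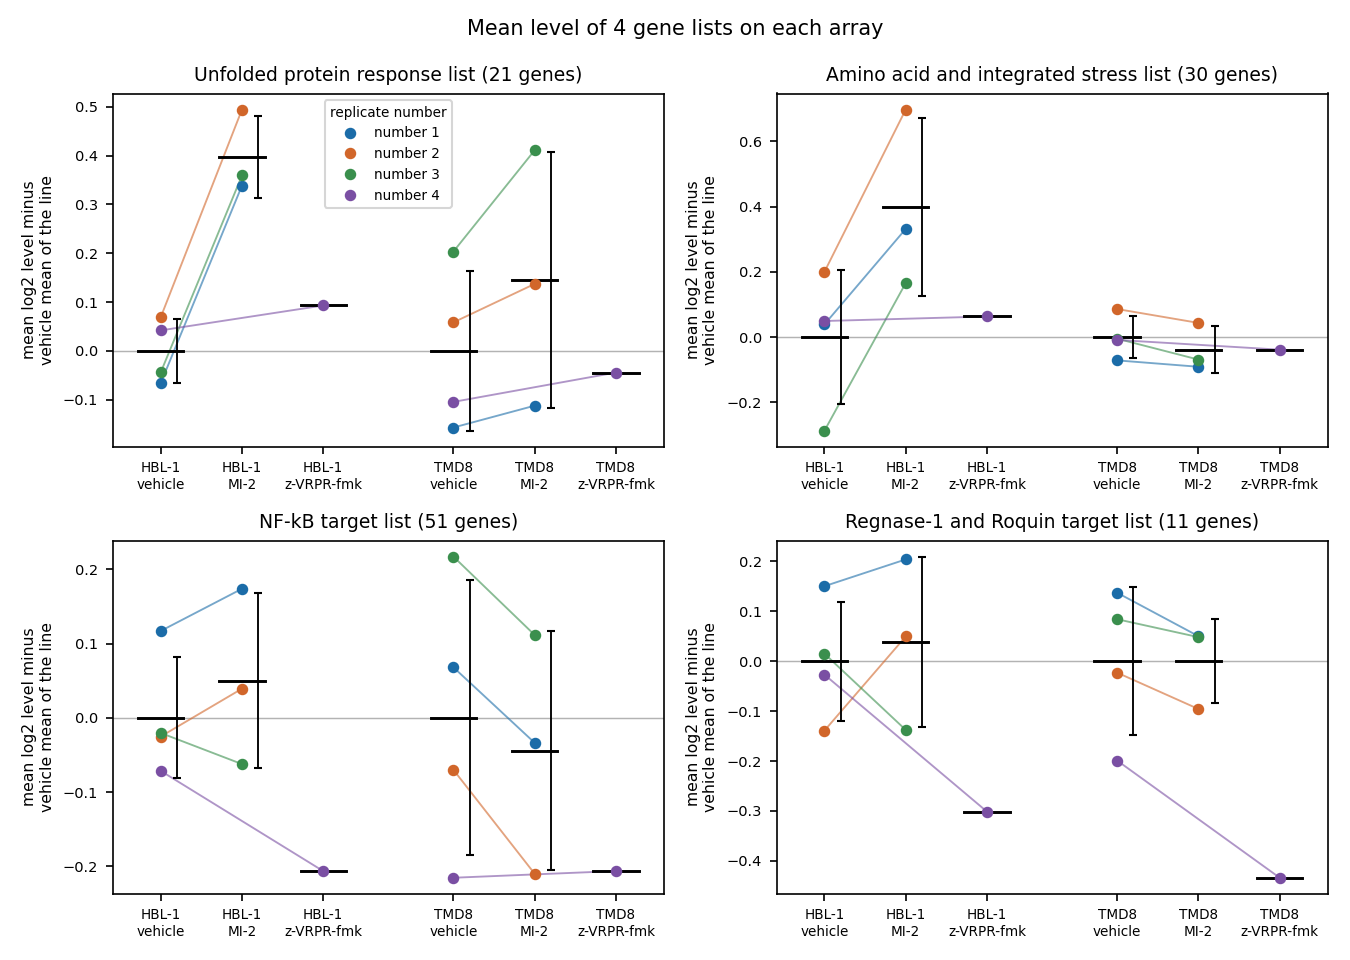
Mean normalized log2 level of 4 gene lists on each array, as the difference from the mean of the line's vehicle arrays, for vehicle (4 arrays), MI-2 (3) and z-VRPR-fmk (1) in each line; points are arrays, thin lines join equal replicate numbers, black bars are group means and error bars SD. With MI-2 in HBL-1 the unfolded protein response mean was 0.40 higher, or 0.29 relative to the median gene with scaling to array medians, where it was -0.04 before subtracting that median.

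With arrays scaled to their medians in place of quantile normalization, the median change of all genes was -0.33 for MI-2 in HBL-1 and -0.18 in TMD8. It was 0.15 for the difference between lines and -0.17 for MI-2 against z-VRPR-fmk. Relative to this median the HBL-1 means were 0.29 for both stress lists, 0.05 for NRF2 antioxidant genes and -0.34 for mitosis genes. In absolute terms this scaling turned the sign of the stress lists (-0.04 for each) and of the NRF2 list (-0.28). That scaling called 0 genes for MI-2 in HBL-1.

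The NRF2 antioxidant list rose in HBL-1 by 0.12 on average, with 17 of 24 members higher (camera adjusted p = 0.00509; adjusted p = 0.107 with an estimated correlation). Its members included KEAP1, the repressor of NRF2 (0.44, SE 0.15), and UGDH (0.46, SE 0.16). This call was lost without MI-2 1 (adjusted p = 0.0948) or vehicle 4 (0.0525). Mitosis genes fell by 0.20 on average, with 27 of 29 lower (camera adjusted p = 0.00232; adjusted p = 0.867 with an estimated correlation). CCNB1, the mitotic cyclin, was at -0.41 (SE 0.20). The mean was -0.09 with the block (0.0241; adjusted p = 0.283 with an estimated correlation). It was -0.19 without MI-2 1 (adjusted p = 0.0835), -0.03 without MI-2 2 (0.802), -0.13 without vehicle 3 (0.144) and -0.09 without vehicle 4 (0.35), but -0.33 without vehicle 2 and -0.37 without MI-2 3, both past the threshold. MYC targets and ribosome biogenesis genes fell by 0.08, with 29 of 33 lower (camera adjusted p = 0.0459; adjusted p = 0.20 with an estimated correlation, 0.101 with the block). They lost the call without MI-2 1 (0.115), MI-2 2 (0.443), vehicle 3 (0.105), vehicle 4 (0.136) and each of TMD8 vehicle 1, MI-2 1 and MI-2 3 (0.0502 to 0.0549).

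NF-kB targets in HBL-1 had a mean change of 0.05, with 33 of 51 higher (camera adjusted p = 0.236), and of -0.32 with scaling to array medians, or 0.01 relative to the median gene. The list passed without vehicle 1 (0.09, adjusted p = 0.0335) or MI-2 3 (0.11, 0.0118), in both cases as higher. TNFAIP3, a feedback inhibitor of NF-kB that MALT1 cleaves, differed by 0.47 (SE 0.20, adjusted p = 0.91) and NFKBIA, the NF-kB inhibitor, by 0.25 (SE 0.14, 0.933). ZC3H12A, which encodes the RNase Regnase-1, differed by 0.33 (SE 0.12, 0.88). MALT1 itself was at -0.08 (SE 0.14), BCL10 at -0.19 (SE 0.15), RELB at 0.01, CYLD at 0.08, IRF4 at 0.03, BCL2A1 (detected on 2 of 3 MI-2 arrays) at -0.01 and MYC at 0.06, with none past the threshold.

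Of the other HBL-1 lists, MAPK and AP-1 immediate early genes had a mean of 0.12 (camera adjusted p = 0.064) and S phase genes -0.10 (0.339). The remaining means were 0.04 for Regnase-1 and Roquin targets, -0.03 for CBM complex genes, 0.01 for MALT1 substrates, -0.02 for JAK-STAT3 targets, -0.03 for heat shock genes and 0.17 for metallothioneins. They were -0.01 for p53 targets, -0.07 for interferon response genes, 0.02 for ABC-type and -0.04 for germinal centre-type lymphoma genes, -0.01 for B cell receptor genes and 0.06 for cholesterol synthesis. Apoptosis regulators were at -0.05, glycolysis at 0.04, chemokines at 0.02 and histone genes at -0.06, and these lists had adjusted p-values of 0.339 or more. CBM genes passed with scaling to array medians (-0.44, or -0.11 relative to the median gene; adjusted p = 0.0291, 0.0291 to 0.967 over 29 alternatives). Mean, median and test differed in sign for MALT1 substrates, p53 targets and B cell receptor genes. With the block interferon response genes (-0.12, adjusted p = 0.0204) and cholesterol synthesis genes (0.11, 0.0135) passed, with adjusted p-values of 0.445 and 0.249 with an estimated correlation. Without vehicle 2 or MI-2 3 the MAPK list (0.0476, 0.00956), the S phase list (-0.21 and -0.23, 0.000797 and 0.00159) and the cholesterol list (0.17 and 0.21, 0.0029 and 0.00159) passed, and without vehicle 2 so did metallothioneins (0.42, 0.0476). The MAPK list also passed without TMD8 vehicle 2, 3 or 4 (0.0405 to 0.0432).

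The same question was asked in TMD8. Unfolded protein response genes rose by 0.15 on average, or 1.11-fold, with 17 of 21 higher (camera adjusted p = 0.00512; adjusted p = 0.974 with an estimated correlation). PDIA4 was at 0.42 (SE 0.17), CRELD2 at 0.40 (SE 0.20) and ARMET at 0.34 (SE 0.13), each with an adjusted p of 0.999. Integrated stress genes had a mean of -0.04 (camera adjusted p = 0.879). IL6, a cytokine that NF-kB induces, was at 6.34 ± 0.79 with vehicle (n = 4) and 5.64 ± 0.67 with MI-2 (n = 3). This difference of -0.70 (SE 0.33) did not pass (adjusted p = 0.999). The mean of the unfolded protein list was 0.09 without vehicle 1 (adjusted p = 0.138), 0.01 without MI-2 3 (0.882) and 0.27 without MI-2 1. With scaling to array medians it was -0.09, or 0.09 relative to the median gene.

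Limma called 0 genes for MI-2 in TMD8, with 816 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0664. The block also gave 0 (1085 unadjusted), and the groups did not overlap for 5.57% of genes against 5.71% by chance. DNAJB4, a heat shock co-chaperone detected on 3 of 4 vehicle arrays, differed by 0.62 (SE 0.17, adjusted p = 0.766) and BAD, a promoter of apoptosis, by -0.41 (SE 0.15, 0.928). MALT1 was at 0.05, BCL10 at 0.20, NFKBIA at 0.02, TNFAIP3 at 0.08, ZC3H12A at 0.18 (SE 0.12), CCL3 at -0.03 (SE 0.42), IRF4 at -0.05 and MYC at -0.03. VPREB3 was detected on 3 of 4 vehicle arrays and 0 of 3 MI-2 arrays, and was at least 1.12-fold lower with MI-2 (adjusted p = 0.901).

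NF-kB targets in TMD8 had a mean of -0.04, with 30 of 51 lower (camera adjusted p = 0.75). With the replicate block the list fell by 0.12 (adjusted p = 0.00106; adjusted p = 0.194 with an estimated correlation), and it passed without vehicle 4 (-0.12, 0.0338). JAK-STAT3 targets, among them SOCS3 (-0.48, SE 0.26) and STAT3 (-0.50, SE 0.29), had a mean of -0.15 (0.437), -0.16 with the block (0.00399; adjusted p = 0.194 with an estimated correlation) and -0.24 without vehicle 2 (0.00659). Interferon response genes had a mean of 0.01 (0.879) that took either sign: -0.22 with the block (6.43e-09; adjusted p = 0.194 with an estimated correlation), 0.22 without vehicle 1 (0.00314), 0.27 without MI-2 2 (0.00111), -0.26 without MI-2 1 (0.00354) and -0.22 without vehicle 4 (0.00547). S phase genes had a mean of -0.11 (0.301), -0.23 without MI-2 1 (0.000862) and -0.21 without vehicle 3 (0.000587). Without vehicle 3 metallothioneins (0.22; 0.42 without it, 0.0247) and mitosis genes (-0.03; -0.16 without it, 0.015) also passed. The other list means were 0.00 for Regnase-1 and Roquin targets and MALT1 substrates, -0.01 for CBM genes, B cell receptor genes and chemokines, 0.02 for MAPK genes and 0.04 for NRF2 genes. They were 0.01 for heat shock genes and p53 targets, 0.02 for ABC-type and -0.07 for germinal centre-type genes, -0.04 for MYC targets and apoptosis regulators, -0.02 for cholesterol synthesis, -0.07 for glycolysis and 0.05 for histones. None of these passed, with adjusted p-values of 0.476 or more, except MYC targets with scaling to array medians (-0.30, or -0.13 relative to the median gene; adjusted p = 0.0365, 0.0365 to 0.977 over 29 alternatives). Mean, median and test differed in sign for the lists within 0.02 of 0 except p53 targets and MAPK genes, and for apoptosis regulators.

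Whether MI-2 acted differently in the lines was tested as the TMD8 change minus the HBL-1 change. The integrated stress list differed by -0.44, with 29 of 30 members lower in this difference (camera adjusted p = 4.08e-12; adjusted p = 0.692 with an estimated correlation). CEBPB differed by -0.80 (SE 0.22), PSPH by -0.90 (SE 0.28), PSAT1, a serine synthesis enzyme, by -0.76 (SE 0.29) and ALDH1L2, a mitochondrial folate enzyme detected on 2 of 3 TMD8 MI-2 arrays, by -1.35 (SE 0.44), each with an adjusted p of 0.999. The unfolded protein list differed by -0.25, with 19 of 21 lower (camera adjusted p = 0.000271; adjusted p = 0.987 with an estimated correlation). Its member DNAJC3 differed by -0.64 (SE 0.25) and HSPA5 by -0.62 (SE 0.40). The integrated stress difference was -0.29 without HBL-1 MI-2 2 (1.07e-05), and the unfolded protein difference -0.12 without TMD8 MI-2 1 (0.205) and -0.38 without TMD8 MI-2 3. Relative to the median gene under scaling to array medians they were -0.37 and -0.20.

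For the difference of the lines limma called 0 genes with or without the block (716 unadjusted without it, 1074 with it), and the smallest adjusted p was 0.795. BRDG1, an adaptor in B cell receptor signalling now called STAP1, was detected on 1 of 3 TMD8 MI-2 arrays and differed by -0.65 (SE 0.18), which was past the threshold adjusted over the germinal centre-type list alone. NF-kB targets differed by -0.09 (0.228), and by -0.14 with the block (0.00128; adjusted p = 0.193 with an estimated correlation). They passed without HBL-1 vehicle 1 (0.0295), HBL-1 MI-2 3 (0.0108), TMD8 MI-2 3 (0.0212) or TMD8 vehicle 4 (0.00452), at -0.13 to -0.17. Mitosis genes (0.17, 0.153), cholesterol synthesis genes (-0.08, 0.482) and interferon response genes (0.07, 0.88) passed with the block at 0.11, -0.13 and -0.11 (0.0412 each; adjusted p of 0.326, 0.304 and 0.6 with an estimated correlation). Mitosis genes also passed at 0.21 to 0.34 without HBL-1 vehicle 1 or 2 or MI-2 3, or TMD8 vehicle 1 or 4 or MI-2 3 (6.6e-05 to 0.0253). Interferon genes passed at 0.29 without TMD8 vehicle 1 (0.0105) and 0.33 without TMD8 MI-2 2 (0.00631), cholesterol genes at -0.19 without HBL-1 vehicle 2 (0.0218) and -0.23 without HBL-1 MI-2 3 (0.00988), and S phase genes at -0.20 without HBL-1 MI-2 2 (0.0106; -0.02 and 0.88 with it). The other lists had adjusted p-values of 0.331 to 0.982, of which NRF2 genes (-0.08) passed with the authors' values (-0.08, adjusted p = 0.0408; 0.0408 to 0.987 over 29 alternatives). Mean, median and test differed in sign for metallothioneins, p53 targets, ABC-type genes, B cell receptor genes, apoptosis regulators and chemokines.

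**Figure D2:**
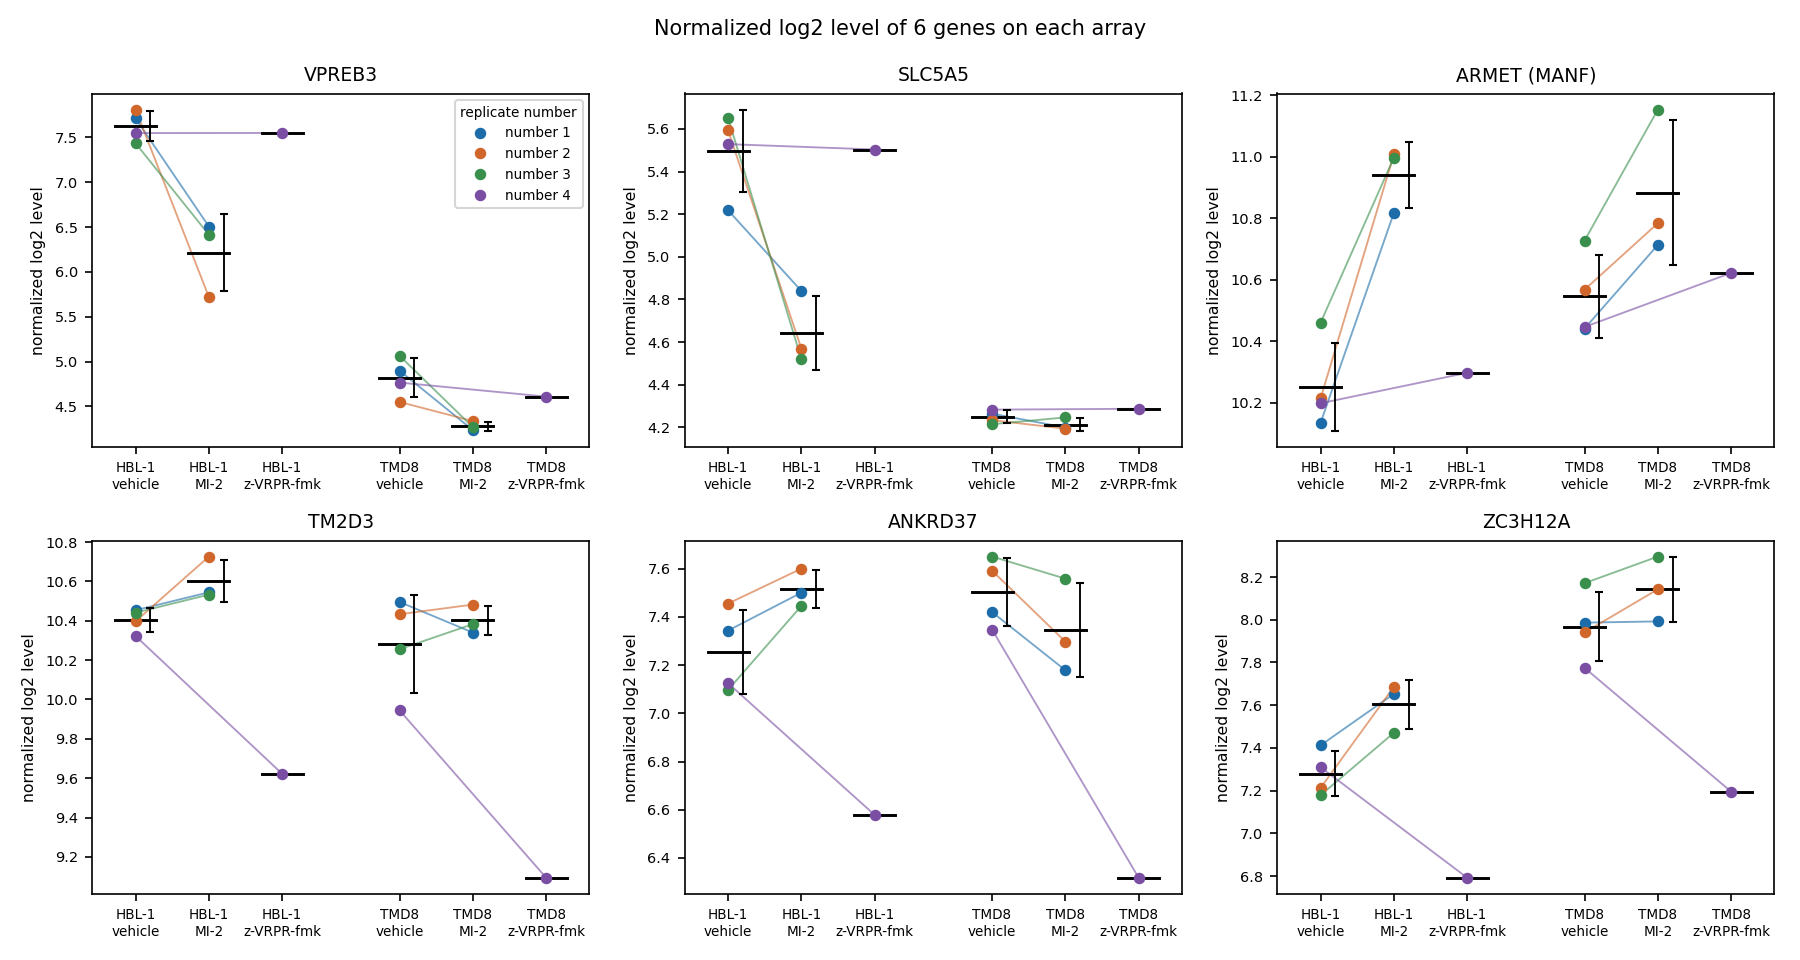
Normalized log2 level of VPREB3, SLC5A5, ARMET (MANF), TM2D3, ANKRD37 and ZC3H12A on each array, for vehicle (4 arrays), MI-2 (3) and z-VRPR-fmk (1) in each line; points are arrays, thin lines join equal replicate numbers, black bars are group means and error bars SD. VPREB3 in HBL-1 went from 7.63 with vehicle to 6.21 with MI-2, and TM2D3 on the z-VRPR-fmk arrays was at 9.62 in HBL-1 and 9.09 in TMD8 against vehicle means of 10.40 and 10.28. In TMD8 SLC5A5 was detected on 0 arrays and VPREB3 on 3 vehicle arrays alone.

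The z-VRPR-fmk comparison asked which transcripts differed between z-VRPR-fmk and vehicle, with 1 array per line set against 4 vehicle arrays and a change taken as equal in the lines. TM2D3, a membrane protein gene, fell by 0.98 (SE 0.14, adjusted p = 0.0311), by 0.78 in HBL-1 and 1.19 in TMD8, and its second probe differed by -0.91. NF-kB targets fell by 0.21 on average, with 40 of 51 lower and -0.21 in each line (camera adjusted p = 1.08e-05; adjusted p = 0.34 with an estimated correlation). Targets of the RNases Regnase-1 and Roquin fell by 0.37, with 10 of 11 lower, -0.30 in HBL-1 and -0.43 in TMD8 (camera adjusted p = 1.08e-05; adjusted p = 0.0963 with an estimated correlation). ZC3H12A was at -0.63 (SE 0.13, adjusted p = 0.451) and fell when adjusted over the Regnase-1 and Roquin list alone, as it did over the MALT1 substrate list alone. TNF, a cytokine gene in the NF-kB and Regnase lists, was at -0.89 (SE 0.32), the costimulatory receptor gene CD40 at -0.50 (SE 0.18) and CD86 at -0.71 (SE 0.22). TNF, CD40 and CD86 did not pass over all genes (adjusted p = 0.9995 for each).

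Limma called 1 gene (737 at an unadjusted p under 0.05), and 0 with the block (597), where TM2D3 had -0.78 and an adjusted p of 1. TM2D3 passed in 17 of 32 alternatives (adjusted p 0.000431 to 1). Its change was -0.78 without the TMD8 z-VRPR-fmk array (1) and -1.19 without the HBL-1 one (0.0603). It also lost its call without HBL-1 vehicle 1 (0.0865) or 2 (0.0596), HBL-1 MI-2 1 (0.0601) or 3 (0.0543), TMD8 vehicle 2 (0.065) or 3 (0.0811) and TMD8 MI-2 1 (0.0562) or 2 (0.0535). ANKRD37, a hypoxia-induced gene, was at -0.93 (SE 0.15, adjusted p = 0.0548), past the threshold adjusted over the glycolysis and hypoxia list alone and, over all genes, without HBL-1 vehicle 3 or 4 or TMD8 MI-2 3 (0.0489, 0.0409, 0.049). TM2D3 and ANKRD37 were called without HBL-1 vehicle 3 or TMD8 MI-2 3, and with CD36 without HBL-1 vehicle 4. PTPRU and LOC100134560, named after their values were seen and detected on 1 and 0 of 4 HBL-1 and on 2 and 0 of 4 TMD8 vehicle arrays, were the calls without the HBL-1 z-VRPR-fmk array, and there were 0 without each of the other arrays that ended the call of TM2D3. By size alone, and not past the threshold, the array lay beyond all vehicle arrays in both lines for HLA-DOA, an MHC class II chaperone (0.87, SE 0.32), ASS1, an arginine synthesis enzyme (0.79, SE 0.39), MGAT3 (0.74, SE 0.24) and the unnamed loci LOC100133583 (0.89, detected on 3 of 4 TMD8 vehicle arrays) and LOC648740 (0.78). It lay below them for CD36, a lipid scavenger receptor (-1.35, SE 0.29, adjusted p = 0.485; 0.0163 without HBL-1 vehicle 4), and the protease gene GZMB (-1.03, SE 0.40) and LOC728835 (-1.45, SE 0.52). Genes beyond all vehicle arrays in both lines numbered 754 above and 832 below, against 702.8 expected by chance for each. MALT1 was at -0.04, BCL10 at -0.02, NFKBIA at -0.22, IRF4 at -0.38 (SE 0.18), CCL3 (detected on 2 of 4 HBL-1 vehicle arrays) at -0.31 and BCL2L1, an inhibitor of apoptosis, at -0.37. IL6 was at -0.96 in TMD8 and was not detected on the HBL-1 z-VRPR-fmk array.

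The replicate block compares each z-VRPR-fmk array with vehicle 4 alone, and with it NF-kB targets were at -0.06 (adjusted p = 0.147; 0.474 with an estimated correlation). Regnase-1 and Roquin targets kept their call at -0.25 (0.000129; adjusted p = 0.139 with an estimated correlation). JAK-STAT3 targets fell by 0.18, with 12 of 15 lower (camera adjusted p = 0.00566; adjusted p = 0.533 with an estimated correlation; -0.10 and 0.17 without the TMD8 z-VRPR-fmk array). Cholesterol synthesis genes rose by 0.18, with 19 of 22 higher (0.00206; adjusted p = 0.56 with an estimated correlation; 0.12 and 0.00509 with the block; 0.09 and 0.235 without the HBL-1 z-VRPR-fmk array), among them IDI1 (0.53, SE 0.19). Mitosis genes rose by 0.22, with 28 of 29 higher (2.69e-05; adjusted p = 0.56 with an estimated correlation), but were at -0.02 with the block (0.865). MAPK genes fell by 0.17, with 17 of 23 lower (0.0193; adjusted p = 0.34 with an estimated correlation; -0.09 and 0.153 with the block), and JUN, a subunit of AP-1, fell adjusted over this list alone (-0.84, SE 0.23). They lost the call without the TMD8 z-VRPR-fmk array (-0.11, 0.226) or TMD8 vehicle 3 (0.0706). Heat shock genes fell by 0.22, with 16 of 23 lower (0.0193; adjusted p = 0.545 with an estimated correlation; -0.11 and 0.0402 with the block, with 0.226 there with an estimated correlation), a call lost without the HBL-1 (0.193) or TMD8 (0.0603) z-VRPR-fmk array or TMD8 vehicle 3 (-0.14, 0.0706). POU2AF1, a B cell coactivator, rose adjusted over the B cell receptor list alone (0.62, SE 0.16).

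ABC-type lymphoma genes fell by 0.13, with 17 of 24 lower (camera adjusted p = 0.0201; adjusted p = 0.143 with an estimated correlation; -0.07 and 0.147 with the block; 0.352 without the HBL-1 z-VRPR-fmk array). Germinal centre-type genes fell by 0.14, with 11 of 17 lower (0.0447; adjusted p = 0.34 with an estimated correlation; 0.0638 with the block), a call held in 11 of 29 alternatives. Their mean was -0.02 without the TMD8 z-VRPR-fmk array (0.897) and -0.26 without the HBL-1 one, and the call was lost without HBL-1 vehicle 2, MI-2 2 or MI-2 3 or TMD8 vehicle 1, 3 or 4 (0.0506 to 0.122). MYC targets fell by 0.08, with 23 of 33 lower (0.0307; adjusted p = 0.34 with an estimated correlation), at -0.02 without the TMD8 z-VRPR-fmk array (0.718), -0.14 without the HBL-1 one and past no threshold without TMD8 vehicle 3 (0.0684). Interferon response genes were at -0.15 (0.106) and at 0.27 with the block (6.77e-10; adjusted p = 0.226 with an estimated correlation), and -0.26 without TMD8 vehicle 4 (0.000215). Metallothioneins were at -0.26 (0.181) and at 0.34 with the block (0.000213; adjusted p = 0.226 with an estimated correlation), -0.37 without TMD8 vehicle 4 (0.0405) and -0.62 without the TMD8 z-VRPR-fmk array (0.0214). S phase genes were at 0.07 (0.183), at -0.09 with the block (0.0298; adjusted p = 0.172 with an estimated correlation), and at 0.10 to 0.16 and past the threshold without HBL-1 vehicle 3, the HBL-1 z-VRPR-fmk array or TMD8 vehicle 4 (0.0351 to 0.0405). Glycolysis genes were at -0.10 (0.181; -0.17 and 0.0382 without the TMD8 z-VRPR-fmk array). CBM genes were at -0.03, MALT1 substrates at -0.08, NRF2 genes at -0.05, integrated stress genes at 0.01, unfolded protein genes at 0.02, p53 targets at -0.04, B cell receptor genes at 0.06, apoptosis regulators at -0.05, chemokines at -0.09 and histones at 0.03, with adjusted p-values of 0.183 or more, and mean, median and test differed in sign for both stress lists.

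MI-2 and z-VRPR-fmk, whose doses are not given in the sources used here, were compared directly as the mean MI-2 effect of the lines minus the z-VRPR-fmk effect. TM2D3 was 2.21-fold higher with MI-2 (1.14, SE 0.14, adjusted p = 0.00648), ZC3H12A 1.84-fold higher (0.88, SE 0.13, 0.028) and ANKRD37 0.98 higher (SE 0.15, 0.028). Regnase-1 and Roquin targets were 0.39 higher, with 9 of 11 in this direction (camera adjusted p = 5.41e-05; adjusted p = 0.152 with an estimated correlation; 0.24 and 0.0012 with the block), and TNF (1.0, SE 0.34) rose adjusted over the list alone. NF-kB targets were 0.21 higher, with 37 of 51 in this direction (5.22e-05; adjusted p = 0.333 with an estimated correlation), and at 0.02 with the block (0.623). With scaling to array medians the NF-kB mean was -0.0021, or 0.17 relative to the median gene. Unfolded protein genes were 0.25 higher, with 18 of 21 in this direction (1.43e-05; adjusted p = 0.314 with an estimated correlation), among them ARMET (0.45, SE 0.14).

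These 3 genes were the ones called (1318 at an unadjusted p under 0.05), and limma called 0 with the block (674). The 3 calls rest on the 2 z-VRPR-fmk arrays: without the TMD8 one the changes were 0.94 for TM2D3 (adjusted p = 0.614), 0.73 for ANKRD37 (0.992) and 0.74 for ZC3H12A (0.979), and 0 genes were called. TM2D3 passed in 27 of 30 alternatives (4.9e-05 to 1) and the other 2 genes in 18 of 30 each (0.0107 to 1). ANKRD37 and ZC3H12A also lost their calls without HBL-1 vehicle 1 (0.0578 each), HBL-1 MI-2 1 (0.0778) or 2 (0.0739), TMD8 vehicle 1 (0.0545), TMD8 MI-2 2 (0.066) or 3 (0.0741), or the HBL-1 z-VRPR-fmk array (0.0508 and 0.108), and TM2D3 was the 1 gene called without each of these except the last. POU2AF1 was at -0.86 (SE 0.17, adjusted p = 0.162; 0.0286 without HBL-1 vehicle 4) and fell adjusted over the B cell receptor list alone. Without HBL-1 MI-2 3 LOC645276 and ZNF669 were called beside the 3 genes, and without HBL-1 vehicle 4 CD36 and POU2AF1 were. Without the HBL-1 z-VRPR-fmk array PTPRU and TM2D3 were called, and these added names other than CD36 and POU2AF1 were chosen after their values were seen.

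Integrated stress genes were 0.17 higher with MI-2 than with z-VRPR-fmk, with 24 of 30 in this direction (camera adjusted p = 0.000641; adjusted p = 0.614 with an estimated correlation; 0.09 and 0.0519 without HBL-1 MI-2 2), but -0.08 with scaling to array medians, or 0.09 relative to the median gene. MAPK genes were 0.24 higher (16 of 23, 0.00151; adjusted p = 0.21 with an estimated correlation; 0.14 and 0.0516 with the block; 0.0506 without the TMD8 z-VRPR-fmk array). NRF2 genes were 0.13 higher (20 of 24, 0.016; adjusted p = 0.21 with an estimated correlation; 0.07 and 0.22 with the block), a call lost without either z-VRPR-fmk array (0.0699, 0.0791) or TMD8 MI-2 2 (0.0516), and were at -0.10 with scaling to array medians, or 0.07 relative to the median gene. ABC-type genes were 0.15 higher (17 of 24, 0.0195; adjusted p = 0.152 with an estimated correlation; 0.07 and 0.22 with the block; 0.234 without the HBL-1 z-VRPR-fmk array), and at -0.09 with that scaling, or 0.08 relative to the median gene. Metallothioneins were 0.46 higher (8 of 8, 0.0284; adjusted p = 0.62 with an estimated correlation) but at -0.35 with the block (0.00396; adjusted p = 0.33 with an estimated correlation). Without the HBL-1 z-VRPR-fmk array they were at 0.10 (0.69), without the TMD8 one at 0.82, and the call was lost without HBL-1 MI-2 1 (0.0956) or 2 (0.0669) or TMD8 MI-2 3 (0.161).

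Mitosis genes were at -0.33 with MI-2 relative to z-VRPR-fmk (28 of 29 lower, camera adjusted p = 4.18e-07; adjusted p = 0.614 with an estimated correlation) and at -0.02 with the block (0.639). S phase genes were at -0.17 (26 of 31 lower, 0.0121; adjusted p = 0.62 with an estimated correlation) and at 0.04 with the block (0.585). The S phase call was lost without HBL-1 MI-2 2 (-0.08, 0.217), TMD8 MI-2 3 (0.0871) or the TMD8 z-VRPR-fmk array (-0.08, 0.457), and was -0.26 without the HBL-1 one. Cholesterol synthesis genes were at -0.16 (19 of 22 lower, 0.0284; adjusted p = 0.62 with an estimated correlation; -0.07 and 0.22 with the block), among them IDI1 (-0.55). They were at -0.08 without HBL-1 MI-2 3 (0.318), -0.07 without the HBL-1 z-VRPR-fmk array (0.403), -0.10 without TMD8 MI-2 1 (0.198) and -0.24 without the TMD8 z-VRPR-fmk array. Interferon genes were at 0.12 (0.187), 0.25 without TMD8 MI-2 2 (0.00343) and -0.44 with the block (4.36e-16; adjusted p = 0.168 with an estimated correlation). Without TMD8 MI-2 2 JAK-STAT3 targets passed too (0.10; 0.16 without it, 0.0159), as did germinal centre-type genes without the HBL-1 z-VRPR-fmk array (0.09; 0.21 without it, 0.0442). CBM genes were at 0.01, MALT1 substrates at 0.09, heat shock genes at 0.21, p53 targets at 0.05, B cell receptor genes at -0.07, MYC targets at 0.02, apoptosis regulators at 0.00, glycolysis at 0.08, chemokines at 0.10 and histones at -0.03, with adjusted p-values of 0.243 or more, and mean, median and test differed in sign for CBM genes and apoptosis regulators.

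**Figure D3:**
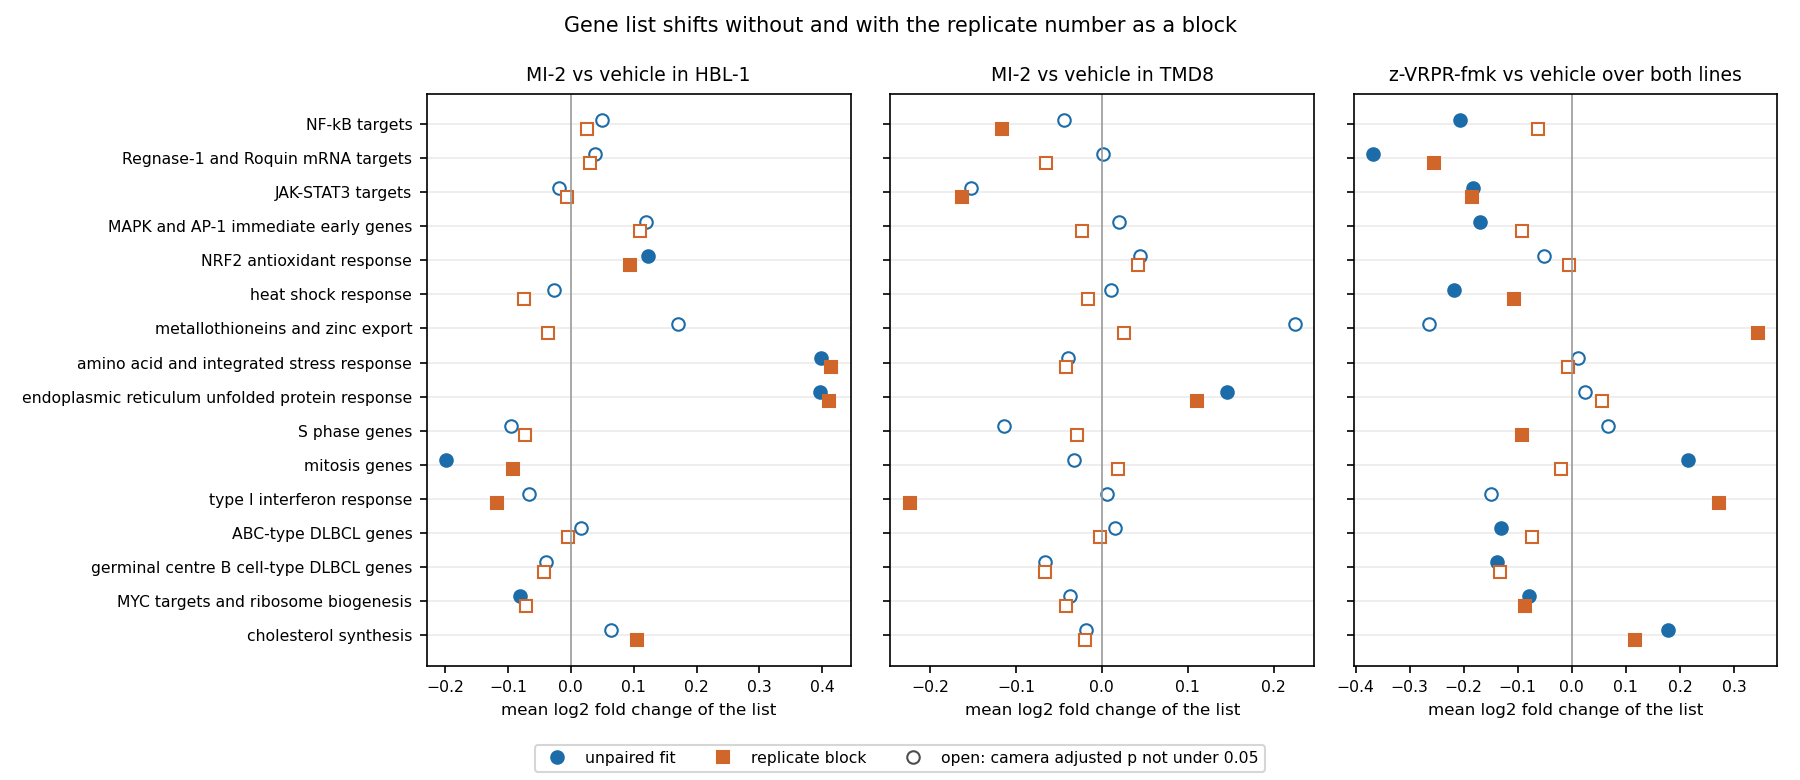
Mean log2 change of 16 gene lists (horizontal axis) for MI-2 in HBL-1, MI-2 in TMD8 and z-VRPR-fmk over both lines; circles are the fit without the replicate block, squares the fit with it, and filled symbols have a camera adjusted p under 0.05. NF-kB targets were at -0.21 with z-VRPR-fmk without the block and at -0.06 with it, and with scaling to array medians the HBL-1 stress lists at 0.40 turned to -0.04, or 0.29 relative to the median gene.

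Across genes, which are not independent replicates, the MI-2 and z-VRPR-fmk changes correlated at r = 0.0928 in HBL-1 and 0.0998 in TMD8 (rho 0.0906 and 0.113). Unchanged groups simulated against the same vehicle arrays gave r = 0.293 in either line, from the shared controls alone. The covariances were 0.00389 and 0.00457 against 0.0142 simulated in each line, differences of -0.0104 and -0.00966. Splitting the vehicle arrays 2 and 2 gave mean correlations of -0.134 (-0.342 to 0.0212) and -0.129 (-0.243 to 0.00169). With vehicle 1 to 3 for MI-2 and vehicle 4 for z-VRPR-fmk, which share no vehicle array and were chosen after the data were seen, the correlations were 0.0447 and 0.0399. The simulated groups were drawn without pairing by number. A state shared by equal numbers lowers the correlation without any drug effect where the vehicle partner of an array enters the other contrast. This holds for the same 4 vehicle arrays and for the split ones. The gap to the simulated values and the negative split values therefore do not show how alike the changes were. The correlation was 0.171 without HBL-1 vehicle 3, 0.269 without HBL-1 vehicle 4, and 0.161, 0.164 and 0.24 without TMD8 vehicle 1, 3 and 4.

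The last comparison was between the lines with vehicle, 4 arrays each. In TMD8 6531 genes differed from HBL-1, 3260 higher and 3271 lower, and 4396 of them by at least 1.5-fold. TCL1A, a coactivator of the kinase AKT, was at least 154-fold higher in TMD8 (adjusted p = 6.45e-17) and not detected in HBL-1. Its paralog TCL1B was 7.93 higher (SE 0.12, detected on 2 of 4 HBL-1 arrays) and CXCL10, an interferon-induced chemokine, 6.73 higher (SE 0.23, detected on 1 of 4). The adhesion gene CDH2 was not detected in TMD8 and was at least 116-fold lower there (6.45e-17), as was PLK5P (at least 62.1-fold lower, 4.64e-16). The cancer-testis gene CTAG2 was at least 76.1-fold lower by a probe not detected in TMD8 (1.8e-17), where another of its probes was detected on 1 of 4 arrays. IL17RB, an interleukin receptor gene, was lower in TMD8 (-7.18, SE 0.17), where it was detected on 2 of 4 arrays.

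NF-kB targets were 0.78 higher in TMD8 on average, with 30 of 51 higher and 6 lower past the threshold, or 33 and 7 adjusted over the list alone (camera adjusted p = 0.000252; adjusted p = 0.544 with an estimated correlation). TNF was 9.21-fold higher (3.20, SE 0.30), IRF4, a plasma cell and ABC-type transcription factor, 3.68-fold (1.88, SE 0.14), IL6 1.92 higher (SE 0.31, detected on 1 of 4 HBL-1 arrays) and TNFAIP3 1.27 higher. MALT1 (-0.12, adjusted p = 0.534) did not pass, BCL10 was 0.42 higher (0.0252) and ZC3H12A 0.69 higher (0.000121). The BCL10 call was lost at 0.39 to 0.42 without HBL-1 vehicle 1, 2 or 4 or TMD8 vehicle 2, 3 or 4 (0.0504 to 0.0695), and with scaling to array medians (0.33, 0.434; 0.00847 to 0.434 over 30 alternatives). That scaling also ended the ZC3H12A call (0.60, 0.0929; 2.95e-05 to 0.0929 over 30 alternatives). Of the regulators of B cell fate, PRDM1 was 9.34-fold higher and BCL6 6.75-fold lower in TMD8. The B cell receptor subunits CD79A (-1.29) and CD79B (-1.46) and the kinase BLK (-4.01) were lower. CCND2, a cyclin gene, differed by -0.57 (0.0131), and by -0.45 without HBL-1 vehicle 1 (0.0547).

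The histone list, which also held deacetylase genes, was 1.68 higher in TMD8, 10 of 14 past the threshold and 1 lower (camera adjusted p = 1.12e-05, or 0.336 with an estimated correlation). Interferon response genes were 0.90 higher, 22 of 34 against 3 lower (0.00063; adjusted p = 0.691 with an estimated correlation). Regnase-1 and Roquin targets were 1.04 higher (7 of 11 against 1, 0.0189; adjusted p = 0.521 with an estimated correlation), MALT1 substrates 0.55 higher (7 of 10 against 0, 0.0189; adjusted p = 0.521 with an estimated correlation) and JAK-STAT3 targets 0.68 higher (9 of 15 against 1, 0.0198; adjusted p = 0.554 with an estimated correlation). S phase genes were at -0.49, 16 of 31 lower and 2 higher (0.00392; adjusted p = 0.706 with an estimated correlation), among them E2F2 (-2.26). Heat shock genes were 0.50 higher (11 of 23 against 3, 0.0327; adjusted p = 0.554 with an estimated correlation), a call lost without HBL-1 vehicle 4 (0.0541) or TMD8 vehicle 3 (0.33, 0.07). Metallothioneins were 1.23 higher (3 of 8 against 0, 0.0327; adjusted p = 0.554 with an estimated correlation), a call lost without HBL-1 vehicle 3 (0.0644) or 4 (0.0738) or TMD8 vehicle 3 (0.0606). Adjusted over the list alone the counts were 23 and 3 for interferon genes, 8 and 2 for Regnase-1 and Roquin targets, 9 and 2 for JAK-STAT3 targets and 2 and 17 for S phase genes.

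The other lists did not pass between the lines. Mitosis genes were at -0.33 (0.057), passing at -0.33 to -0.46 without HBL-1 vehicle 1 or 2, HBL-1 MI-2 2 or 3, TMD8 vehicle 1, 2 or 4 or TMD8 MI-2 3 (0.00737 to 0.0488). MAPK genes were at 0.62 (0.0776; 0.66 and 0.0383 without TMD8 vehicle 4) and glycolysis genes at -0.48 (0.0776; 0.0439 without HBL-1 vehicle 4). Integrated stress genes were at -0.21 (0.104; -0.30 and 0.0326 without HBL-1 vehicle 3) and cholesterol genes at 0.19 (0.104; 0.30 and 0.0261 without HBL-1 vehicle 2, 0.27 and 0.0446 without TMD8 vehicle 1). Germinal centre-type genes were at -0.42 (0.108). ABC-type genes had a mean of 0.01 and a median of -0.24, B cell receptor genes -0.25, CBM genes -0.17, chemokines 0.52, unfolded protein genes -0.16, NRF2 genes 0.01, MYC targets -0.01 and p53 targets -0.02 with a median of 0.10. Apoptosis regulators had a mean of 0.13 and a median of -0.17. The test pointed lower for ABC-type genes, NRF2 genes and p53 targets and higher for MYC targets and apoptosis regulators, and the adjusted p-values of these lists were 0.108 to 0.923. Scaling to array medians called 4003 genes between the lines, 42.9% of them higher in place of 49.9%.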

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

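In this part the tests on same-numbered arrays, on the scaling, on the arrays numbered 4, on TMD8 vehicle 4 and on an effect shared by the lines, the sign flips and the splits of same-numbered differences, were chosen only after the results were seen.

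MI-2 moved the integrated stress list by -0.437 more in TMD8 than in HBL-1 and the unfolded protein list by -0.252, both by a test of the difference itself (camera adjusted p 4.08e-12 and 0.000271; adjusted p of 0.692 and 0.987 with an estimated correlation). Permuting residuals among the vehicle and MI-2 arrays gave a difference as large in 3 of 100 arrangements for the integrated stress list, the real one included. The highest other value was 0.537, larger in size than the real difference. For the unfolded protein list it was 15 of 100, with a highest other value of 0.401, so chance cannot be excluded. Neither count takes account of the pairs, so the smaller count cannot exclude chance either. Between same-numbered arrays the unfolded protein differences were 0.405, 0.425 and 0.403 in HBL-1 and 0.0448, 0.0788 and 0.208 in TMD8, a gap of -0.301. Those of the integrated stress list were 0.293, 0.498 and 0.453 against -0.0196, -0.0425 and -0.0641, a gap of -0.457. Of the 10 splits of the 6 differences 1 gave a gap as large for each list, the real one (highest others 0.170 for the unfolded protein list and -0.248 for the integrated stress list), which are too few for a share under 0.05.

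The higher unfolded protein and integrated stress lists with MI-2 in HBL-1 were weighed first. A state shared by same-numbered arrays would leave differences between them near 0, but the lowest of the 6 was 0.293, and those of the unfolded protein list were 0.405, 0.425 and 0.403. With the share of probes detected as a covariate over 14 arrays the shift of the unfolded protein list was 0.382 (SE 0.136). That of the integrated stress list was 0.288 (SE 0.118), and both argue against that share as the whole cause. The lowest shift relative to the median gene over the scalings was 0.286, so both lists rose relative to that gene under each scaling. Subtracting the median removes an overall offset between arrays by construction, and before it median scaling turned the sign of both lists. Whether the lists rose in absolute terms therefore depends on the scaling and cannot be decided here. No other of the 35 splits of the HBL-1 arrays gave an unfolded protein mean as large (0.397 against -0.338, 1 of 35 with the real one). For the integrated stress list 3 of 35 did, the real one included (0.398 against 0.418). These splits take no account of the pairs. Among the 8 splits parting all 3 pairs the real means were the largest (largest others -0.322 and -0.327), but 8 are too few for a share under 0.05. Chance can therefore not be excluded for either list. A stress response to MI-2 in HBL-1 may be the source, as a hypothesis, and whether it goes through MALT1 was not tested here. The HBL-1 z-VRPR-fmk array differed from vehicle 4 by 0.0510 for the unfolded protein list and 0.0139 for the integrated stress list. A single array cannot decide this question.

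The lower NF-kB and Regnase-1 and Roquin target lists on the z-VRPR-fmk arrays were weighed next, against a state of the arrays numbered 4, since the z-VRPR-fmk array of each line shares that number with vehicle 4. The lists share members, among them IL6, TNF, NFKBIZ, NFKBID and IER3, so they are not independent of each other. In TMD8 the NF-kB list differed from vehicle 4 by 0.00903, which is consistent with such a state as the source there. In HBL-1 it differed by -0.135, against an SD of 0.0445 among same-numbered MI-2 differences, and 1 pair cannot decide. The Regnase-1 and Roquin targets differed from vehicle 4 by -0.255 on average, -0.275 in HBL-1 and -0.235 in TMD8. The SE of this mean, 0.087, was taken from the spread of same-numbered MI-2 differences. Those ran from -0.153 to 0.189 in HBL-1 and from -0.0871 to -0.0359 in TMD8. Only if z-VRPR-fmk pairs vary likewise does this argue against that state as the whole cause. With 1 z-VRPR-fmk array per line that could not be checked. An effect of z-VRPR-fmk on these targets may remain, as a hypothesis, and a fault of the single arrays stays open.

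The NF-kB list in TMD8 with MI-2, lower only within pairs, was weighed last. By construction the means with and without the block (-0.116 and -0.04) differ through vehicle 4 alone, which has no MI-2 partner and lay at -0.215 from the vehicle mean. Without it and without the block the list passed (adjusted p = 0.0338; 0.00106 to 0.977 over 29 alternatives), and without each other single array it did not (lowest 0.157), which is consistent with vehicle 4 as the source of the disagreement, while why it was low stays open. The same-numbered differences were -0.102, -0.140 and -0.106 in TMD8 and 0.0568, 0.0644 and -0.0419 in HBL-1. The list was thus not lower in every HBL-1 pair, but 3 pairs with both signs cannot decide on an effect of MI-2 shared by the lines. The test of the difference between the lines did not pass without the block (camera adjusted p = 0.228). It passed with the block at the preset correlation (0.00128) and not with an estimated one. Of the 4 sign patterns of the 3 differences, 1 gave a mean as large, the real one (-0.116 against 0.048), which are too few for a share under 0.05, and this replaced a first test on unpaired means, in which 5 of the 8 splits parting all 3 pairs gave a mean as large (real -0.04, largest other 0.159).

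For counts of called genes, 2 of the 35 splits of the HBL-1 arrays gave 2 or more genes, so chance cannot be excluded. The highest other count, 27, came from setting vehicle 3, vehicle 4 and MI-2 3 against the rest, which parts no pair and points to a structure of the arrays by replicate number. Among the other splits parting all 3 pairs the highest was 0. Any split reaches a real count of 0, so the splits say nothing about chance in TMD8 (35 of 35, the highest being 10 for vehicle 3, vehicle 4 and MI-2 3) or for the difference of the lines (100 of 100, the highest being 49). Between the lines 1 of 35 splits gave as many as 6531 genes, the real one, and the highest other gave 0. Every other split mixes the lines in both groups, so line differences enter its spread and keep its count low. The share of 1 of 35 argues against a chance split of these arrays. It does not cover chance between cultures, since the labels do not say that the arrays came from separate ones. The number of lists called at the preset correlation for MI-2 in HBL-1 (5) was reached by 16 of 35 splits, with a highest other of 10. In TMD8 the number (1) was reached by 31 of 35, with a highest other of 15. Chance can therefore not be excluded for either number of lists. Among the other splits parting all 3 pairs the highest number of lists was 3 in each line. The unfolded protein mean in TMD8 (0.145) was reached by 16 of 35 splits, with a highest other of 0.329, so over all splits chance cannot be excluded. Among the 8 splits parting all 3 pairs the real mean was the largest (0.145 against 0.119; same-numbered differences 0.0448, 0.0788 and 0.208), and 8 are too few for a share under 0.05.

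Lists and genes, 107 in each line, were tested for 1 of the 4 vehicle arrays standing far from the others. These 214 tests share arrays and members and are not independent. In 10 of them 1 array stood far from the others, where chance at 1 in 20 gives 10.7. In HBL-1 these were vehicle 1 for CCL4L1 (5.16 against a mean of 4.34 for the others, which did not detect it) and IRF4 (9.37 against 8.78), and vehicle 2 for the p53 target list (6.98 against 6.85). Vehicle 3 was high for TCL1A (4.36 against 4.27), which was not detected there, and vehicle 4 was low for HYOU1 (7.61 against 7.86), CD40 (8.26 against 8.64) and IER3 (4.82 against 5.28). In TMD8 they were vehicle 1 for NFKBIZ (11.9 against 11.5), vehicle 2 for BCL6 (6.96 against 7.57) and vehicle 3 for the mitosis list (8.24 against 8.74).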

How the results depend on the processing

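In this part the replicate block with an estimated correlation, the block as a random effect, the fits without both arrays of a number and the matched vehicles were chosen only after the data were seen. Of 3736 checks of single genes 3643 kept their side of the threshold and, where called, their direction, while 80 lost and 13 gained a call. Directions were not compared where neither the report nor the alternative had a call, and some of those turned sign. Of 4128 checks of lists, counted in the same way, 3867 were unchanged and 156 lost and 82 gained a call. A further 23 turned sign with a call in the report or in the alternative. Of 224 checks of counts 62 moved by over 1.5 times, and of 34 checks of correlations 10 moved and 2 turned sign. Where the number of arrays or of genes tested does not show it, the cause was not tested. The files name no slide, so the slide as a block was not run. Signal near background limits dim genes such as SLC5A5.

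Called genes for MI-2 in HBL-1, 2 in the report, numbered 1 with normexp and an offset of 50 or with array weights (VPREB3 in each), and 0 with median scaling, with only the arrays compared, with the replicate block and without both HBL-1 arrays numbered 2. Without both TMD8 arrays numbered 3 there was 1, VPREB3. With no background correction and with the authors' values they were VPREB3 and UCHL1, the latter named after its values were seen, and with trended and robust eBayes VPREB3 and ARMET. For MI-2 in TMD8, 0 in the report, 1 was called without a detection filter, with a detection p under 0.01, with the mean of a gene's probes and with the random block, in each case LOC100134560, also named after its values were seen, and 2 with every probe on its own, of LOC100134560 and MBNL2. For z-VRPR-fmk, 1 in the report, 2 were called with normexp and an offset of 50, cyclic loess, the mean of probes, trended and robust eBayes, array weights, the mean of the 2 lines' contrasts and the random block (TM2D3 and ANKRD37 in each). It was 0 with median scaling, only the arrays compared, the replicate block, and without both HBL-1 arrays numbered 2 or both TMD8 arrays numbered 3. For MI-2 against z-VRPR-fmk, 3 in the report, 0 were called with median scaling and with the replicate block, and 1, TM2D3, without both HBL-1 arrays numbered 2 or both TMD8 arrays numbered 3. Median scaling called 4003 genes between the lines.

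Median scaling moved the means for MI-2 in HBL-1 to -0.278 for NRF2 genes, -0.0363 for integrated stress genes and -0.0383 for unfolded protein genes. It moved unfolded protein genes to -0.0926 in TMD8 and to -0.0543 for the difference of the lines. For MI-2 against z-VRPR-fmk it gave -0.00211 for NF-kB targets, -0.10 for NRF2 genes, -0.0762 for integrated stress genes, -0.0673 for interferon genes and -0.0944 for ABC-type genes. Their shifts relative to the median gene are in the report where a list passed. Without a detection filter Regnase-1 and Roquin targets were at 0.216 in that comparison.

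With the replicate block NF-kB targets were at -0.116 and interferon genes at -0.224 for MI-2 in TMD8, and interferon genes at -0.106 for the difference of the lines. For z-VRPR-fmk it gave -0.063 for NF-kB targets, 0.345 for metallothioneins, -0.0914 for S phase genes, -0.0208 for mitosis genes and 0.273 for interferon genes. For MI-2 against z-VRPR-fmk it gave 0.0183 for NF-kB targets, -0.350 for metallothioneins, 0.0398 for S phase genes and -0.444 for interferon genes. Beyond the calls the report gives with the block, it changed no other call.

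With an estimated correlation no list call of any comparison held. The means are the same by construction, 0.398 and 0.397 for integrated stress and unfolded protein genes in HBL-1, 0.145 for unfolded protein genes in TMD8, -0.437 and -0.252 for the difference of the lines, -0.206 and -0.368 for NF-kB and Regnase-1 and Roquin targets with z-VRPR-fmk, and 0.209 and 0.388 for MI-2 against it. The block with an estimated correlation kept the integrated stress and unfolded protein calls in HBL-1. Outside the comparison of the lines it ended every other list call, 24 of them with the same direction and 3 with the sign turned. These included unfolded protein genes in TMD8 (0.110), integrated stress and unfolded protein genes for the difference (-0.457 and -0.301), NF-kB and Regnase-1 and Roquin targets and mitosis genes with z-VRPR-fmk (-0.063, -0.255 and -0.0208) and NF-kB targets, Regnase-1 and Roquin targets, metallothioneins and S phase genes for MI-2 against it (0.0183, 0.237, -0.350 and 0.0398).

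Without both TMD8 arrays numbered 3, 8 list calls were lost and 2 gained. Lost were unfolded protein genes in TMD8 (0.0802), MAPK, heat shock, germinal centre-type and MYC target lists with z-VRPR-fmk, metallothioneins and S phase genes for MI-2 against it and heat shock genes between the lines. Gained were MAPK genes in HBL-1 and mitosis genes for the difference. Without both HBL-1 arrays numbered 2, 3 were lost (MYC targets in HBL-1, germinal centre-type genes with z-VRPR-fmk and S phase genes for MI-2 against it) and 2 gained (mitosis and cholesterol genes between the lines). Germinal centre-type genes with z-VRPR-fmk also lost the call with no background correction, the authors' values, cyclic loess, a detection p under 0.01, no detection filter and the mean of probes. Metallothioneins between the lines lost it with the first 2 of these and with a detection p under 0.01, which also ended heat shock genes there and MYC targets in HBL-1. The mean of probes ended MYC targets in HBL-1 and cholesterol genes for MI-2 against z-VRPR-fmk, and cyclic loess MYC targets with z-VRPR-fmk. No detection filter ended NRF2 genes in HBL-1 and, for MI-2 against z-VRPR-fmk, metallothioneins and Regnase-1 and Roquin targets. Median scaling ended NRF2 genes in HBL-1, unfolded protein genes in TMD8 and for the difference, and NRF2, integrated stress and ABC-type genes for MI-2 against z-VRPR-fmk. Calls were gained with median scaling by CBM genes in HBL-1, MYC targets in TMD8, interferon genes with z-VRPR-fmk (-0.225) and in MI-2 against it, glycolysis genes with z-VRPR-fmk and between the lines, and MAPK genes between the lines. The authors' values added NRF2 genes for the difference, the mean of probes glycolysis genes with z-VRPR-fmk, normexp with an offset of 50 mitosis genes between the lines, and no detection filter integrated stress, mitosis, cholesterol and glycolysis genes there.

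The correlation of the MI-2 and z-VRPR-fmk changes in HBL-1 was 0.0131 with no background correction, 0.00692 with the authors' values and -0.134 with split vehicles. In TMD8 it was 0.201 with median scaling, 0.0423 with the authors' values, -0.129 with split vehicles and 0.0399 with matched vehicles.

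Leaving out each array in turn gave 1 to 3 called genes for MI-2 in HBL-1, 0 to 3 for z-VRPR-fmk and 0 to 5 for MI-2 against it. NF-kB means ran from -0.0115 to 0.106 in HBL-1 and from -0.122 to 0.0389 in TMD8. Unfolded protein means ran from 0.0124 to 0.274 in TMD8 and from -0.385 to -0.123 for the difference of the lines, and interferon means in TMD8 from -0.260 to 0.266. The correlations ran from 0.0194 to 0.269 in HBL-1 and from 0.0775 to 0.240 in TMD8.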

Other observations

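The overlap of the MI-2 changes and the contrasts within equal numbers in this part were chosen only after the results were seen.

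At an unadjusted p under 0.05, 18 genes were higher with MI-2 in both lines, of 453 in HBL-1 and 379 in TMD8, where independent lists would share 9.77. They included ARMET, PDIA4, the stress-induced enzyme gene FICD and SEC61A1, which encodes the channel that brings proteins into the endoplasmic reticulum. Lower in both were 15, of 485 and 437, against 12.1 for independent lists, among them VPREB3, which no TMD8 MI-2 array detected. FICD and SEC61A1 were named after their values were seen.

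Interferon response genes differed by 0.567 between the z-VRPR-fmk array and vehicle 4 in TMD8, and metallothioneins by 0.691. In HBL-1 the same contrasts were -0.0219 and -0.00104. Between MI-2 and same-numbered vehicle arrays the interferon genes differed by -0.116, -0.369 and -0.186 in TMD8 and by -0.131, -0.144 and -0.0793 in HBL-1. JAK-STAT3 targets differed by -0.172, -0.133 and -0.183 in TMD8 and by -0.00357, 0.00786 and -0.0236 in HBL-1. Spike-in control probes were detected at 0% to 3.26% per array, and probes without a gene name at 30.4% to 39.3%.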
